A study of Mus musculus with 6 samples.

How the data were processed

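Messenger RNA libraries of 32D cells with retroviral human U2AF1, WT or S34F, were sequenced, with 3 libraries per group. Per the labels' protocols, RNA was extracted on micro columns and libraries were made with a directional kit. The authors deposited whole-number read counts per Ensembl gene, 1 column per library. Per the submitters' processing notes, HISAT2, featureCounts and the build mm10 were used. Versions, the strand setting, the annotation release and the rule for reads with several matches are not given in the sources used here. Reads of near-identical copies and of overlapping genes on opposite strands can therefore be split or shared in a way that could not be checked. Among the changed named genes, the largest overlaps were of Sqstm1 with Mrnip, Angptl6 with A230050P20Rik and Cebpd with Spidr, each on the opposite strand. They covered 17.3%, 16.8% and 15.0% of the exon bases of the named gene. Mean levels were 3.90 CPM for Mrnip, 0.520 for A230050P20Rik and 48.2 for Spidr. Those of Sqstm1, Angptl6 and Cebpd were 1011, 22.3 and 22.5 CPM, so only Spidr lay above the gene it overlaps.

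The columns were matched to samples by their names, and groups and replicate numbers came from the sample titles. Totals lay between 16509899 and 19129250 counts per library, 1 count equalled 0.0523 to 0.0606 CPM, and 3 counts, the limit a count of 0 allows, 0.157 to 0.182 CPM. Symbols came from the deposited table, and 27 that a spreadsheet had turned into dates were restored by gene ID. Coordinates, GC content and exon length came from GENCODE release M21 on the same build, which held 54495 of the gene IDs and 99.987% of the counts. GC content was known for 13433 of the 13444 tested genes.

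Counts were tested in edgeR 4.0.16 under R 4.3.3 with TMM normalisation, filterByExpr and the robust quasi-likelihood F test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment at 0.05. The design held the genotype only, with 4 residual degrees of freedom. Standard errors were the log2 fold change divided by the root of its F value. CPM values are TMM-normalised, and fold values are 2 to the power of the fitted log2 fold change. Single values per library were compared with an exact permutation test.

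Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over 36 lists, and again with an estimated correlation and with fry. The lists held 899 entries, of which 3 matched no gene and 1 was matched by an older symbol. They covered 3 oxidative stress lists, 8 DNA repair and p53 lists, and lists of mitochondria, metabolism, stress, RNA, proliferation, hematopoiesis, other cell types and immune genes. Adjustment over the list alone is given beside that over all genes.

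Named genes followed a rule. They were U2af1, the 12 largest rises and 12 largest falls among changed genes with a mean of at least 2 CPM and all 3 S34F libraries on one side of the WT libraries, and the 10 with the smallest p by the same criteria. Predicted and clone-based symbols were left out. From each list came up to 4 changed members, or the member with the smallest p where none changed. This gave 73 genes, 51 of them changed, and 2 of the 73 are not reported here. The tests, the alternatives listed first, the lists and this rule were chosen before the data were examined.

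The alternatives were RLE and upper-quartile factors, library totals alone, no count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, glmTreat against 1.5-fold, and each library left out. Chosen after seeing the data were the sum of WT replicates 2 and 3, offsets removing each library's loess trend (span 0.5) with GC content or with GC content and length, and the first 2 of these together. Library pairs were compared by a chi-square of counts over genes with at least 20 counts in the pair.

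The procedure was tested on simulated counts of 13444 genes with 200 changed. It called 110 genes, 12 of them unchanged, and none had the wrong sign. It recovered 7.5% of 1.5-fold, 59.7% of 2-fold and 80.3% of 4-fold changes, so most small changes go undetected with these libraries. In a simulated shift of 0.3 on the log2 scale of 1 list, camera found that list (adjusted p = 3.07e-04), while the estimated correlation and fry did not (adjusted p = 0.282 and 0.194). Simulated counts were drawn independently for each gene and library. They held no correlation between genes, no pair as close as WT replicates 2 and 3 and no GC trend. How camera with the preset correlation performs on correlated genes was therefore not tested by simulation. On the measured libraries, splits that mixed the genotypes gave between 6 and 17 lists with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.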

Results

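Gene expression was measured by RNA sequencing in 32D cells, a mouse line of myeloblast-like cells that needs interleukin-3 to grow. The cells had been transduced with a GFP retrovirus carrying human U2AF1, a splicing factor that binds the 3' end of introns, either as the wild-type protein (WT) or with the S34F substitution found in myeloid malignancies (S34F). There were 2 groups with 3 libraries each, and the title of the series names oxidative stress and DNA repair as its subject. Gene counts totalled 18538164, 19129250 and 16716979 in S34F replicates 1 to 3 and 16744957, 16509899 and 18119760 in WT replicates 1 to 3. At these depths 1 count equalled between 0.0523 and 0.0606 CPM, the unit of counts scaled to library size.

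WT replicates 2 and 3 were much closer to each other than any other pair of libraries. Their biological coefficient of variation, the spread left after counting noise, was 3.16%, against 16.5% to 21.5% in the other pairs within a group and 21.6% to 29.4% between the groups. Their counts still differed by more than sampling noise (chi-square per degree of freedom 2.30), which argues against reads of 1 library divided at random. It does not show that they came from separate cultures. They were counted as separate libraries, and counts are also given with both summed into 1. The labels do not name separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

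**Figure D1:**
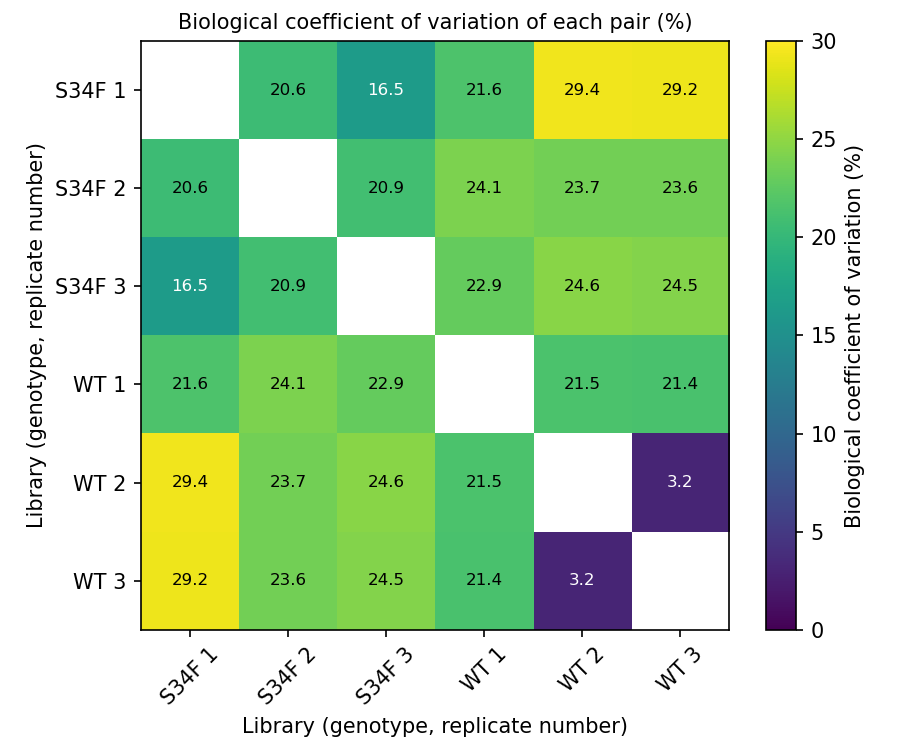
Biological coefficient of variation in percent for each pair of the 6 libraries, with libraries named by genotype and replicate number on both axes and the value written in each square. WT replicates 2 and 3 stand apart at 3.16%, and every other pair lies at 16.5% or above.

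U2af1 (ENSMUSG00000061613, chromosome 17, 31647081 to 31658892, mm10) was counted at 91.9, 57.3 and 91.7 CPM in S34F replicates 1 to 3 and at 97.9, 58.6 and 56.9 CPM in WT replicates 1 to 3. The difference was smaller than the spread between replicates, with a log2 fold change of 0.17 ± 0.25 (SE, n = 3 per group, edgeR adjusted p = 0.721). These counts do not check the labels, since both groups received a U2AF1 construct and gene counts do not show the allele.

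In S34F cells 213 genes rose and 80 fell of 13444 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The rises with the smallest p-values were Hk3, given below, and the following 8 genes, among genes with a mean of at least 2 CPM and no predicted or clone-based symbol. Tyrobp, a signalling adaptor of myeloid receptors, rose 3.89-fold from 14.9 ± 0.995 to 58.1 ± 5.71 CPM (SD, n = 3 per group, adjusted p = 0.00199). Fcer1g, the common gamma chain of Fc receptors, rose 2.52-fold (adjusted p = 0.00309). Lcn2, an iron-siderophore binding protein of neutrophil granules, rose 6.42-fold from 87.3 ± 11.3 to 560 ± 153 CPM (adjusted p = 0.00292). Sqstm1, the autophagy receptor p62, rose 2.73-fold from 542 ± 51.4 to 1480 ± 145 CPM (adjusted p = 0.00344). The actin-capping protein gene Capg rose 2.30-fold, the lysosomal sialidase gene Neu1 2.25-fold, Renbp 2.25-fold and the noncoding RNA Zfas1 2.04-fold, with adjusted p-values of 0.00292, 0.00689, 0.00689 and 0.00689.

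Apart from Lcn2, the 12 largest rises by fold among the named genes started from low levels in WT, at 6.59 CPM or less. Hk3, the hexokinase of myeloid cells, rose 7.62-fold to 10.3 ± 2.12 CPM (SD, n = 3, adjusted p = 0.00689). Chdh, choline dehydrogenase, rose 6.28-fold and Angptl6 5.80-fold, and the transcription factor gene Zfp503 rose 6.08-fold. The inhibitory receptor gene Pirb rose 4.82-fold, Slfn2 4.54-fold, the chemokine receptor gene Ccr1 4.43-fold and the aldehyde dehydrogenase gene Aldh3b1 4.33-fold. Slc11a1, a metal transporter of phagosomes, and the actin-binding protein gene Avil rose 12.4-fold and 11.6-fold but were uneven among the S34F libraries, with SDs of 3.80 CPM on a mean of 5.10 and of 8.61 CPM on a mean of 13.3. The potassium channel gene Kcnh2 had 301 counts in the S34F libraries and 6 in the WT libraries, a ratio of 47.4 after scaling to library totals (exact 95% interval 21.5 to 130.2, for counting error only).

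Among the genes that fell, Ctla2a, a cathepsin inhibitor homologue, had the smallest p and fell 3.68-fold from 52.3 ± 6.06 to 14.2 ± 2.20 CPM (SD, n = 3 per group, adjusted p = 0.00292). The potassium channel gene Kcnj2 fell 3.70-fold from 120 ± 42.8 to 32.5 ± 4.06 CPM (adjusted p = 0.0131). Pdcd1, which encodes the receptor PD-1, fell 6.61-fold and Pdzd2 5.08-fold. The falls of Vmn2r99, Asz1, Ablim1, Nhsl2, Gimap1, Islr and Fam161b lay between 4.78-fold and 2.48-fold. Rps27rt fell 3.76-fold, but it is a near-identical retrotransposed copy of Rps27, and reads can be assigned to either. Summed over both genes the count was 419, 379 and 366 CPM in S34F replicates 1 to 3 and 416, 444 and 439 CPM in WT replicates 1 to 3. All 293 changed genes had the 3 S34F libraries on one side of the 3 WT libraries, as had 27.1% of all genes tested, where chance gives 10% for 6 independent libraries. With WT replicates 2 and 3 averaged into 1 the share was 30.8%, where chance gives 20%.

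The count of changed genes depended on single libraries of both groups. It was 20 without S34F replicate 1, 50 without S34F replicate 3, 19 without WT replicate 2 and 22 without WT replicate 3, against 337 without S34F replicate 2 and 1177 without WT replicate 1. Without WT replicate 1 the WT group held only WT replicates 2 and 3, so gene and list tests of that fit rest on the closest pair of libraries. With WT replicates 2 and 3 summed, 16 genes rose and 4 fell, all of them among the 293. Of the 51 changed genes picked by the rule for named genes, 13 passed with both summed, namely Kcnh2, Hk3, Lcn2, Tyrobp, Capg, Fcer1g, Sqstm1, Renbp, Neu1, Zfas1, Kcnj2, Ctla2a and Rps27rt. The other 38 had between 0.881 and 1.09 of their log2 fold change, with a median SE of 0.268 instead of 0.236, so the changes stayed about as large while the spread grew and the libraries were fewer. Fold changes also followed the GC content of the transcripts (Spearman's rho 0.316 across genes, which are not independent replicates), and after removal of this trend in each library 119 genes rose and 44 fell, 151 of them among the 293. Of the 51 genes, 15 lost their call with it, namely Slc11a1, Angptl6, Asz1, Fam161b, Msrb1, Msra, Atm, Bax, Psrc1, mt-Cytb, mt-Co2, Sel1l, Jund, Casp2 and Fcgr1. Of these, 8 had at least 0.9 of their log2 fold change, namely Slc11a1, Angptl6, Fam161b, Msra, Psrc1, Sel1l, Casp2 and Fcgr1, and the lowest shares were 0.625, 0.633 and 0.650, for mt-Cytb, mt-Co2 and Jund. The median SE was 0.148 instead of 0.162, and all 15 had an unadjusted p of 0.0285 or less.

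**Figure D2:**
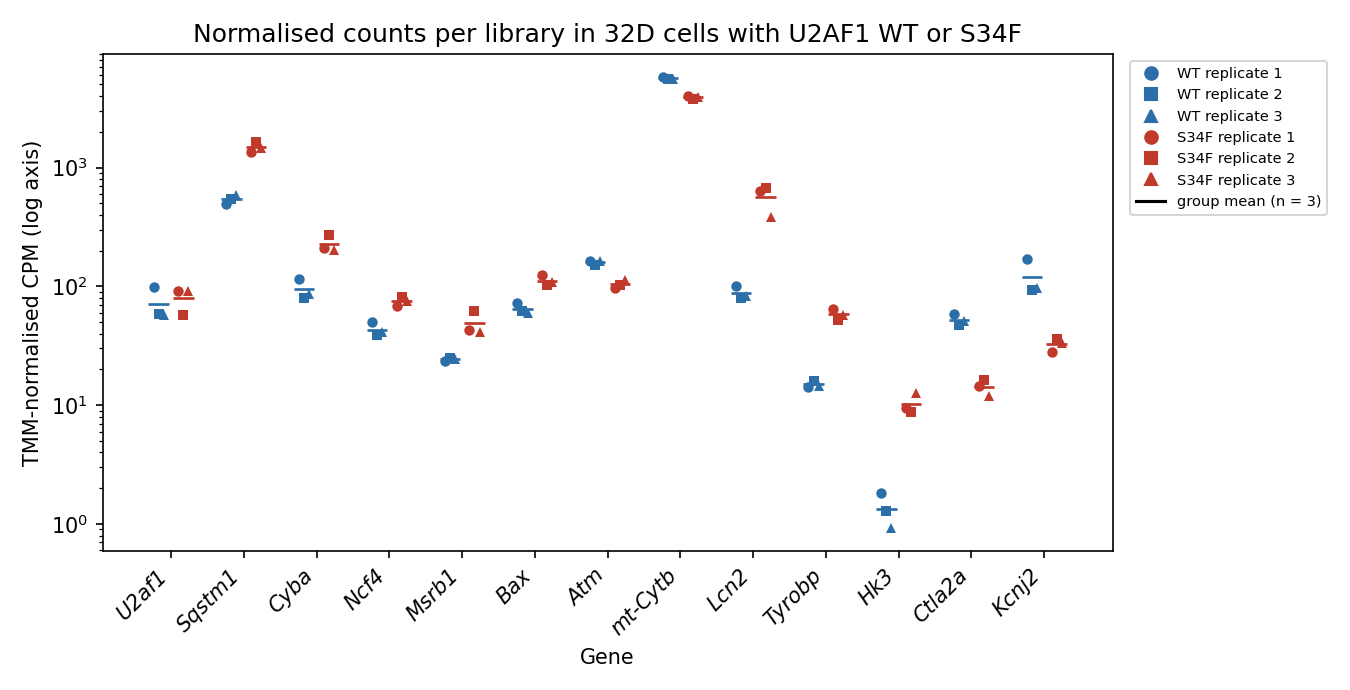
TMM-normalised CPM on a log axis for 13 genes in each library, with WT in blue, S34F in red, a marker shape for each replicate number and a bar at the mean of 3 libraries. Lcn2 lies at 87.3 CPM on average in WT and 560 in S34F, while U2af1 overlaps between the groups.

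Of the 36 gene lists, 10 passed camera with the preset correlation. Splits of the libraries that mixed the genotypes gave between 6 and 17, so these list calls alone do not set the genotypes apart. The 3 lists of oxidative stress genes held 60 genes that could be tested, of which 5 rose, none fell and 55 did not pass the test. Sqstm1 rose in the list of NRF2 targets and glutathione metabolism, which was higher as a group (24 genes, median log2 fold change 0.15, camera adjusted p = 0.00978). That call did not hold with an estimated correlation between genes, where the adjusted p was 0.770, nor without S34F replicate 1 or S34F replicate 2, where it was 0.0789 and 0.0701. The mean log2 level of the list, relative to the WT mean, was 0.342, 0.365 and -0.014 in S34F replicates 1 to 3 and 0.147, -0.082 and -0.065 in WT replicates 1 to 3, so S34F replicate 3 was not higher. Within this list 5 genes rose when p was adjusted over the list alone. Among antioxidant enzymes, the methionine sulfoxide reductase genes Msrb1 and Msra rose 2.01-fold and 1.56-fold (adjusted p = 0.0286 and 0.0492). The list of 24 genes did not pass (camera adjusted p = 0.173). Its adjusted p was 0.0379 without S34F replicate 3, 0.0392 without WT replicate 1 and 0.536 without S34F replicate 1. In the list of producers of reactive oxygen species, the NADPH oxidase subunit genes Cyba and Ncf4 rose 2.42-fold and 1.74-fold (adjusted p = 0.0170 and 0.0276). The list of 12 genes did not pass (camera adjusted p = 0.118). Its adjusted p was 2.54e-05 without S34F replicate 3 and 0.935 without S34F replicate 2. Its mean log2 level relative to the WT mean was 0.383, 0.878 and -0.333 in S34F replicates 1 to 3. In WT replicates 1 to 3 it was 0.121, -0.069 and -0.052. Adjusted over the list alone, 3 genes rose among antioxidant enzymes and 3 among the producers. With WT replicates 2 and 3 summed, Sqstm1 kept its call (adjusted p = 0.0190) and Msrb1, Msra, Cyba and Ncf4 did not (adjusted p = 0.119, 0.208, 0.0728 and 0.130), with log2 fold changes of 1.012, 0.654, 1.193 and 0.743 against 1.004, 0.645, 1.273 and 0.797 before.

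Few DNA repair genes passed the test. In the 7 lists of repair and checkpoint genes, 1 gene rose and 1 fell of 147 tested. Over all genes 293 of 13444 changed, so few calls were also to be expected among these 147. Atm, the kinase that signals double-strand breaks, fell 1.54-fold from 160 ± 7.26 to 104 ± 7.61 CPM (SD, n = 3 per group, adjusted p = 0.0286). In the lists of nucleotide excision repair, mismatch repair, homologous recombination, the Fanconi anemia pathway and end joining, edgeR called 0 of 104 genes. At an unadjusted p under 0.05 there were 12 genes, DESeq2 called 3 and limma-voom 0. In the last 4 of these lists the members with the smallest p were Rfc2, Wrn, Wdr48 and Xrcc5, with log2 fold changes of -0.53, -0.58, -0.23 and 0.43 that did not pass (adjusted p = 0.0655, 0.110, 0.221 and 0.201).

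None of the 7 repair and checkpoint lists passed as a group. Camera gave adjusted p-values of 0.432 for base excision and single-strand break repair, 0.915 for nucleotide excision repair, 0.227 for mismatch repair and 0.689 for homologous recombination. The values were 0.464 for the Fanconi anemia pathway, 0.773 for end joining and 0.0576 for checkpoint signalling, whose 21 genes had a median log2 fold change of -0.15. Adjusted over the list alone, 1 gene of these lists rose and Atm and Rfc2 fell. The p53 target genes were higher as a group (24 genes, median log2 fold change 0.26, camera adjusted p = 0.00168; adjusted p = 0.606 with an estimated correlation). Among the p53 target genes Bax, which opens the outer mitochondrial membrane in apoptosis, rose 1.72-fold and Psrc1 1.76-fold (adjusted p = 0.0257 and 0.0497), and 7 rose and 1 fell when adjusted over the list alone. With WT replicates 2 and 3 summed, Atm, Bax and Psrc1 did not keep their calls (adjusted p = 0.132, 0.119 and 0.166), with log2 fold changes of -0.630, 0.744 and 0.884 against -0.618, 0.784 and 0.819 before.

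**Figure D3:**
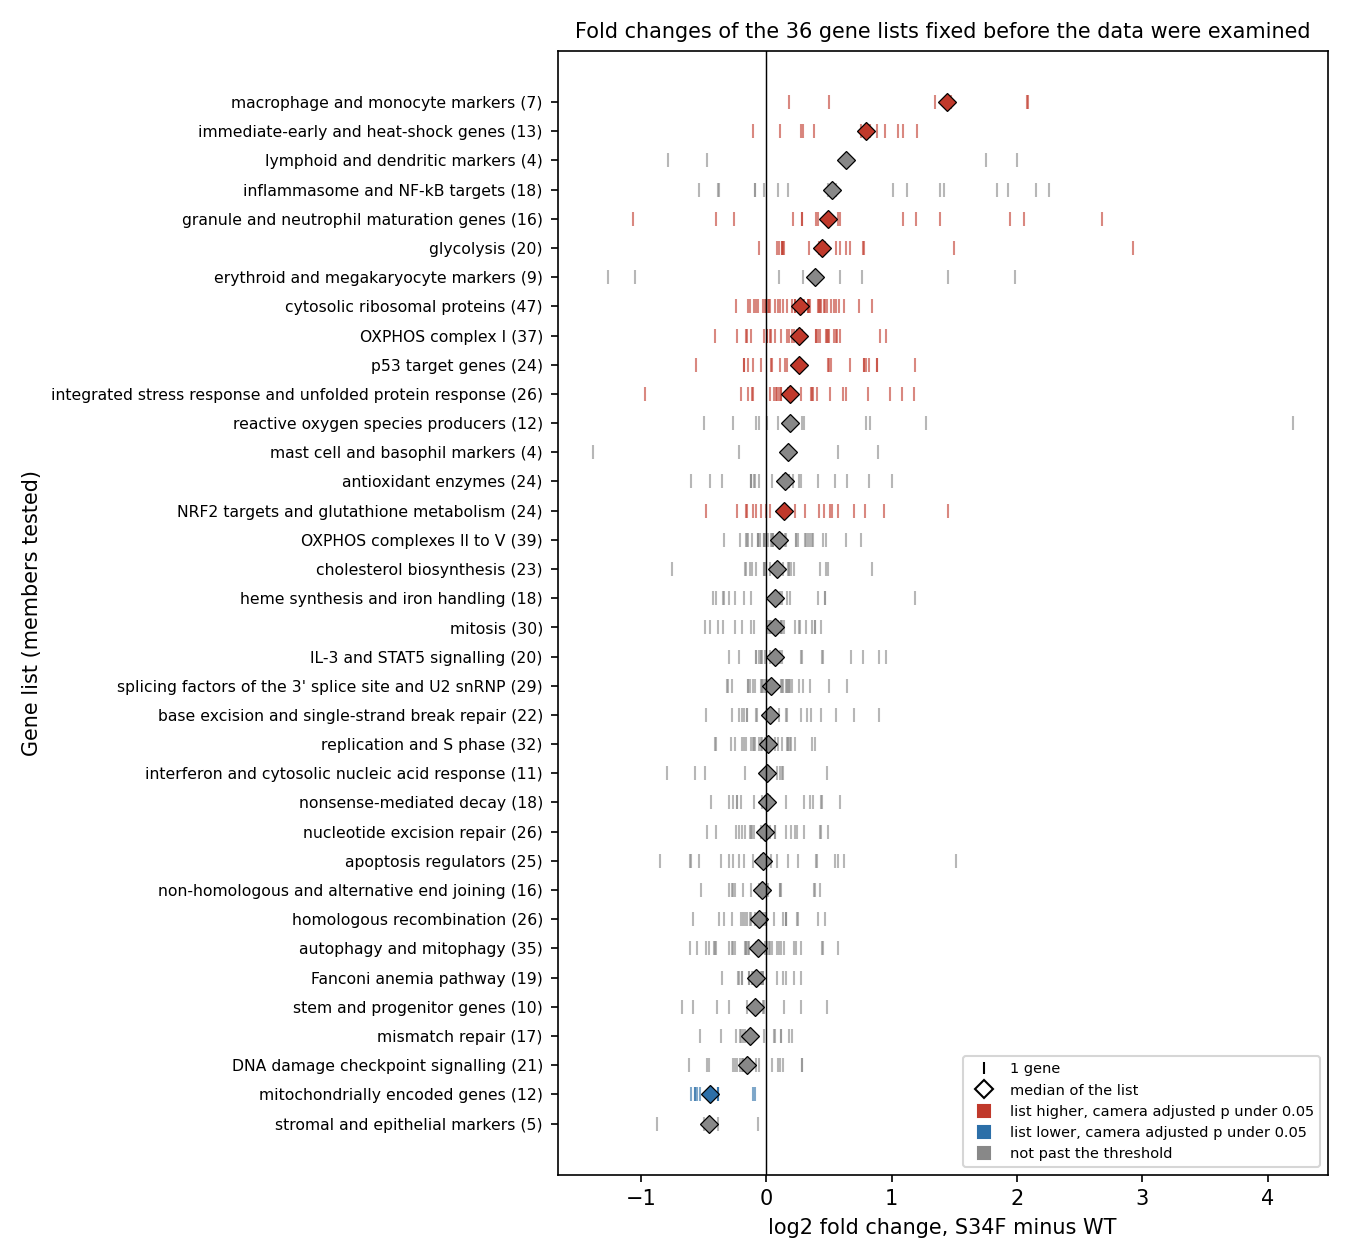
Log2 fold changes (S34F minus WT) of the tested members of the 36 gene lists, a tick for each gene and a diamond at the median, ordered by median. Red and blue mark lists that passed camera with a preset correlation, 9 higher and 1 lower; with an estimated correlation 0 passed.

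Genes encoded by the mitochondrial genome were lower in S34F cells. All 12 tested had a negative log2 fold change, with a median of -0.44 (camera adjusted p = 2.25e-05; adjusted p = 0.628 with an estimated correlation), and 2 fell, or 8 when adjusted over the list alone. mt-Cytb fell 1.44-fold from 5651 ± 155 to 3920 ± 123 CPM and mt-Co2 1.48-fold (SD, n = 3 per group, adjusted p = 0.0492 for both). Their share of all counts was 2.10% ± 0.072 in S34F and 2.89% ± 0.137 in WT (SD, n = 3, exact permutation p = 0.10, two-sided, the smallest this design allows). With the GC trend removed the median was -0.20 and the adjusted p 0.105, and mt-Cytb and mt-Co2 had log2 fold changes of -0.330 and -0.358 instead of -0.528 and -0.566. mt-Co2 was counted at only 24.6 CPM in S34F, and nuclear copies of mitochondrial sequence can share reads with it.

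Nuclear genes of respiratory complex I moved the other way (37 genes, 31 positive, median log2 fold change 0.27, camera adjusted p = 0.00107; adjusted p = 0.818 with an estimated correlation). By mean log2 level relative to the WT mean, S34F replicate 2, at 0.082, lay below WT replicate 1, at 0.223. No single gene passed in the 76 genes of complexes I to V by edgeR, where 17 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0. Ndufa2 and Uqcrq had log2 fold changes of 0.95 and 0.76 (adjusted p = 0.0563 and 0.0560). Complexes II to V did not pass as a list (adjusted p = 0.182; 0.0149 without S34F replicate 2 and 1.40e-05 without WT replicate 1), nor did autophagy and mitophagy (adjusted p = 0.284), where Gabarap had a log2 fold change of 0.44 (adjusted p = 0.0599). In autophagy 1 gene rose and 3 fell when adjusted over the list alone, and no gene of complexes I to V passed.

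Glycolysis genes were higher as a group (20 genes, 19 positive, median log2 fold change 0.45, camera adjusted p = 7.00e-06; adjusted p = 0.703 with an estimated correlation). Hk3 was the member that rose over all genes tested, and 9 rose when adjusted over the list alone. Cholesterol biosynthesis (adjusted p = 0.687) and heme and iron handling (adjusted p = 0.915) did not pass. Their members with the smallest p were Idi1 and Slc25a37, with log2 fold changes of -0.75 and 0.47 (adjusted p = 0.103 and 0.0662). In heme and iron handling 1 gene rose and 1 fell when adjusted over the list alone.

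The list of integrated stress and unfolded protein responses was higher (26 genes, median log2 fold change 0.19, camera adjusted p = 0.00107; adjusted p = 0.770 with an estimated correlation). Trib3, a pseudokinase induced by ATF4, rose 2.26-fold, Ppp1r15a, a phosphatase subunit that restores translation, 2.12-fold, and the ER degradation factor gene Sel1l 1.55-fold (adjusted p = 0.0221, 0.0216 and 0.0492). Adjusted over the list alone, 5 genes rose. Immediate-early and heat-shock genes, which respond to the handling of cells, were also higher (13 genes, median log2 fold change 0.80, camera adjusted p = 0.00265; adjusted p = 0.781 with an estimated correlation; adjusted p = 0.0701 without S34F replicate 2). Their groups overlapped: the mean log2 level relative to the WT mean was 0.702, 1.213 and 0.245 in S34F replicates 1 to 3 and 0.982, -0.563 and -0.418 in WT replicates 1 to 3. Klf6 rose 2.13-fold and Jund 1.74-fold (adjusted p = 0.0387 and 0.0492), and these 2 genes also passed when adjusted over the list alone. With the GC trend removed the log2 fold change of Jund went from 0.798 to 0.519 and did not pass (adjusted p = 0.118).

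Splicing factors of the 3' splice site did not pass as a list (29 genes, adjusted p = 0.689), nor did nonsense-mediated decay (18 genes, adjusted p = 0.975). Sf3a2 and Nbas, their members with the smallest p, had log2 fold changes of 0.65 and -0.44 (adjusted p = 0.138 and 0.0684). Cytosolic ribosomal protein genes were higher (47 genes, 39 positive, median log2 fold change 0.27, camera adjusted p = 1.27e-05; adjusted p = 0.770 with an estimated correlation). No single gene of these 3 lists passed by edgeR, of 94 tested: 30 had an unadjusted p under 0.05, DESeq2 called 10 and limma-voom 2. Rps28 had a log2 fold change of 0.84 (adjusted p = 0.0543), and 11 ribosomal protein genes rose and 1 gene of nonsense-mediated decay fell when adjusted over the list alone.

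Replication (32 genes, adjusted p = 0.856), mitosis (30 genes, adjusted p = 0.545) and apoptosis regulators (25 genes, adjusted p = 0.890) did not pass. Mcm6 and Aurka had log2 fold changes of -0.41 and 0.39 (adjusted p = 0.152 and 0.120). Casp2, an initiator caspase, fell 1.52-fold (adjusted p = 0.0499). In interleukin-3 and STAT5 signalling (20 genes, adjusted p = 0.162; 0.0498 without S34F replicate 3), Id1 had a log2 fold change of 0.90 (adjusted p = 0.0543). Among apoptosis regulators 2 rose and 2 fell, and 3 genes of interleukin-3 and STAT5 signalling rose, when adjusted over the list alone.

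Genes of granules and neutrophil maturation were higher (16 genes, median log2 fold change 0.49, camera adjusted p = 0.00239; adjusted p = 0.770 with an estimated correlation; adjusted p = 0.0711 without S34F replicate 1). The rise of the list was in 2 of 3 libraries, with mean log2 levels relative to the WT mean of 0.883, 0.739 and -0.151 in S34F replicates 1 to 3 and 0.123, -0.097 and -0.025 in WT replicates 1 to 3. Lcn2 and Cebpd, a transcription factor of granulocytes, rose, Cebpd by 2.61-fold (adjusted p = 0.0267). Markers of macrophages and monocytes were higher too (7 genes, all positive, median log2 fold change 1.44, camera adjusted p = 2.16e-04; adjusted p = 0.606 with an estimated correlation). Fcgr1, the high-affinity IgG receptor, rose 2.55-fold (adjusted p = 0.0355). Stem and progenitor genes did not pass as a list (10 genes, adjusted p = 0.222), while the ETS factor gene Fli1 fell 1.59-fold (adjusted p = 0.0276). Adjusted over the list alone, 3 granule genes and 3 macrophage markers rose and 2 stem and progenitor genes fell.

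Markers of other cell types did not pass as lists with all libraries and no GC correction. The adjusted p was 0.773 for mast cells and basophils, 0.220 for erythroid cells and megakaryocytes, 0.232 for lymphoid and dendritic cells and 0.107 for stromal and epithelial cells. The stromal and epithelial list was lower with the GC trend removed (adjusted p = 0.0471, median log2 fold change -0.63 instead of -0.45), with no count filter (adjusted p = 0.0135) and without S34F replicate 2 (adjusted p = 0.00518). Without WT replicate 1 the erythroid and lymphoid lists passed as higher (adjusted p = 0.0415 and 0.0450). Cd74, the invariant chain of MHC class II, rose from 34.5 ± 17.3 to 138 ± 30.8 CPM (SD, n = 3 per group, adjusted p = 0.0257). Ctsg, Pf4 and Acta2 had log2 fold changes of 0.58, 1.45 and -0.87 (adjusted p = 0.106, 0.0699 and 0.120). The interferon list (11 genes, adjusted p = 0.773) and the list of inflammasome and NF-kB targets (18 genes, adjusted p = 0.222; 0.00531 without S34F replicate 3 and 9.16e-04 without WT replicate 1) did not pass, and Bst2 and Casp1 had log2 fold changes of 0.48 and -0.53 (adjusted p = 0.146 and 0.0857). Adjusted over the list alone, 1 mast cell, 2 erythroid or megakaryocyte and 1 lymphoid or dendritic marker rose. Median, mean and camera direction differed in sign for nucleotide excision repair, heme and iron handling, replication, apoptosis regulators, mast cell markers and the interferon list, none of which passed.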

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

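The sum of WT replicates 2 and 3 and the GC and length corrections were chosen after seeing the data. No changed gene turned its direction in any setting. All 293 had the S34F libraries on one side of the WT libraries, so fits that leave out or sum libraries had little room to turn one. The median log2 fold change of all genes moved by at most 0.03 between scalings. The main count of 293 changed genes became 763 with no count filter, 1082 by DESeq2 and 1418 with the replicate block. It became 10 against 1.5-fold, 163 with the GC trend removed, 177 with GC and length trends removed, 20 with WT replicates 2 and 3 summed and 15 with the GC trend removed and both summed. Leaving out 1 library gave between 19 (without WT replicate 2) and 1177 genes (without WT replicate 1), with 20 without S34F replicate 1, 50 without S34F replicate 3 and 22 without WT replicate 3. Calls that kept their side in each of these 6 fits numbered 14. RLE, upper-quartile, totals alone, 1 CPM and limma-voom gave 286, 241, 228, 285 and 271. Whether the replicate numbers pair the libraries stays open. Deviations correlated by 0.332, 0.159 and 0.072 for equal numbers 1 to 3, and by -0.259 to 0.153 for unequal numbers. S34F replicate 3 correlated best with WT replicate 2, by 0.080, but WT replicates 2 and 3 are too alike for this to decide.

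Of 10 lists that passed, 0 passed with an estimated correlation (smallest adjusted p = 0.606, 2 lists at an unadjusted p under 0.05) and 0 with fry (smallest 0.0532, 7 unadjusted); leaving out 1 library gave between 8 and 15. The NRF2 list had adjusted p = 0.770 and 0.356 in these tests, 0.113 with the GC trend removed and both WT libraries summed, and between 0.000378 and 0.0789 without 1 library. The p53 list had 0.606 and 0.0532. Checkpoint signalling passed as lower with upper-quartile factors (0.0385), totals alone (0.0364) and no filter (0.0390). Without 1 library, antioxidant enzymes lay between 0.0379 and 0.536 and producers of reactive oxygen species between 2.54e-05 and 0.935. Without WT replicate 1 the WT group held only WT replicates 2 and 3, with the smallest coefficient of variation of any pair (3.16%). The 1177 genes and 15 lists of that fit rest on this small spread. Without WT replicate 2 or 3 the counts of genes were 19 and 22, near the 20 with both summed. Fewer libraries also leave fewer degrees of freedom, and other causes were not tested. Of the 51 changed genes picked by the naming rule, calls kept were 50 with RLE, 44 with upper-quartile factors, 43 with totals alone, 51 by DESeq2, 44 by limma-voom, 36 with the GC trend removed and 13 with both WT libraries summed. Depth limits genes of few counts such as Kcnh2, with 6 counts in WT.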

Other observations

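In this part the tests of explanations and of other splits and the lysosomal, proteasome and Zfp lists were chosen after the results were seen, unlike the edgeR tests of single genes. Lysosomal genes, a list written after some of them were seen to rise, were mostly higher: of 48 tested, 41 had a positive log2 fold change, with a median of 0.34. Of these 6 rose, against 3 with the GC trend removed (median 0.27) and 1 with WT replicates 2 and 3 summed (median 0.33). Besides Neu1 these included Man2b2, an alpha-mannosidase, with a log2 fold change of 0.76 ± 0.10 (SE, n = 3 per group, edgeR adjusted p = 0.0159), the cathepsin gene Ctsz at 1.03 ± 0.20 (adjusted p = 0.0408), the proton pump subunit gene Atp6ap1 at 0.54 and Cd63 at 0.54. That lysosomal genes are higher in S34F cells is a hypothesis that these data leave open. Camera with an estimated correlation gave p = 0.0238, but on a list chosen for the rise, so this p is no independent test.

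Nfe2l1, a transcription factor that induces proteasome genes, rose with a log2 fold change of 0.92 (edgeR adjusted p = 0.0128), and a candidate consequence is a rise of the proteasome. The median log2 fold change of the 31 subunit genes was 0.038, with quartiles of -0.11 and 0.21, and edgeR called 0 of them. Camera with a preset correlation gave p = 0.43. The median was 0.073 with the GC trend removed and -0.013 with WT replicates 2 and 3 summed. These values show no rise of the subunits as a group, while a small rise is left open. Genes with Zfp and a number as symbol, mostly zinc finger factors, were lower (310 genes, median log2 fold change -0.23, camera p = 9.38e-08; p = 0.195 with an estimated correlation), with 7 that fell and 1, Zfp503, that rose. With the GC trend removed the median was -0.136, 2 fell and 1 rose. With WT replicates 2 and 3 summed the median was -0.211 and edgeR called 0, with 38 at an unadjusted p under 0.05.

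Splitting the 6 libraries into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 293 changed genes, as many as in 1 of the 10 splits, and the highest other gave 56. For gene lists by camera with a preset correlation, the real split gave 10, the highest other 17, and 4 of the 10 splits gave as many as the real one. The splits that mixed the genotypes gave between 6 and 17 lists. The number of lists called with the preset correlation therefore does not set the genotypes apart from other splits of these libraries.

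WT replicates 2 and 3 differed far less than any other pair. Reads of 1 library divided at random would give a chi-square per degree of freedom of about 1, and the value was 2.30. Their coefficient of variation of 3.16% is consistent with 2 samples of 1 culture, which the labels do not settle. If so, the WT group held 2 independent samples and the count of 20 genes applies.

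Fold changes followed GC content: genes that rose had a median of 54.2% and genes that fell 44.3%, against 49.1% in all tested. Removing each library's trend left a median share of 0.904 of the log2 fold change of the changed genes, which argues against the trend as their whole cause. In the 142 genes that lost their call the median size went from 0.71 to 0.59, with a median SE of 0.14 before. The median of the mitochondrially encoded genes moved from -0.44 to -0.20, so for them the GC trend and genotype cannot be told apart, since only part of the change remains. The trend itself had rho of 0.156 to 0.229 in S34F libraries and -0.308 to -0.004 in WT libraries, and whether it comes from genotype or from library preparation was not tested.

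Lists of macrophage markers and of granule genes were higher by camera with a preset correlation but not with an estimated one (adjusted p = 0.606 and 0.770), and the granule list was not higher in S34F replicate 3. Of their 7 and 16 tested genes, 1 and 2 passed over all genes. Macrophages, monocytes or neutrophils mixed into S34F libraries could raise such genes. Of 20 listed macrophage and monocyte markers, 2, Cd68 and Fcgr1, were above every WT library in every S34F library, and 6 were at 0 counts in all libraries. Macrophages or monocytes mixed into the S34F libraries cannot be told apart from a change within the cells, since most of these markers are near the count floor. Neutrophils mixed in would bring S100a8, S100a9, Camp, Ltf and Ngp, abundant in these cells, along with Lcn2. Summed, these 5 genes were counted at 17.8, 3.97 and 1.73 CPM, scaled to library totals, in S34F replicates 1 to 3 and at 6.39, 3.45 and 4.08 in WT replicates 1 to 3. Their rise over the WT mean was at most 2.56% of that of Lcn2, in S34F replicate 1, which argues against neutrophils as the source of the Lcn2 rise. A shift of expression within the 32D cells stays open and was not tested.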
